A study of Mus musculus with 2 samples.

How the data were processed

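The series holds 2 single-cell RNA libraries of mouse kidney, 1 for cisplatin-treated Rnls knockout mice given empty mesonanoparticles and 1 for those given RP81-loaded mesonanoparticles. Per the labels, the tissue was digested with Liberase and DNase I, filtered, cleared of red cells and debris, and sequenced as droplet libraries; Cell Ranger 3.0.0 and Seurat 4.1 with builds mm10 and GRCm38 are named as the processing tools.

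The deposited table used here holds whole-number values that are a score and not raw counts: the authors had made them with a depth correction (SCTransform corrected counts), which brings each cell towards 1 common depth. Their total and gene number per cell equal the corrected totals listed in the deposited metadata for all 39276 cells, and the totals lie between 1584 and 3201. The metadata columns with the library, the authors' cell class, and UMIs and genes per cell before correction are of another kind, labels and depths, per the file headers. Field separators were lost in that table, and 657 cells for which UMIs and genes could not be parted with 1 reading were left out of depth summaries and depth windows. The log-transformed and scaled tables were not used here. The table holds 17847 gene symbols, of which 17642 were found in GENCODE M21 (GRCm38) for coordinates.

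Libraries were grouped by the labels, and the authors' 22 classes were used as they stand. Shares of cells per class were given exact Clopper-Pearson 95% intervals. The 10 genes with the highest level over all other cells, among those with a count in at least 25% of the cells, were taken as the genes that lead a class or pool. Sizes were not compared where more than 5 of these differed beyond 1.5-fold between the libraries, a limit set after the values were seen, and leading genes are not given as results of their class. A list member, in the empty-particle library, or a named gene, in the library with the higher level, was read as background where its level was at or below the lowest among T cells, endothelium and TAL, its own lineage left out. Those classes make some of these genes, so such a level does not show that a gene is absent. Nor does a level above it show that a class makes the gene. In T cells, 0 of 20 proximal tubule transport genes were read as background by this rule. The infiltrating and M1 classes were pooled as macrophages after the data were examined, and the Plac8+ class, led by collagen genes, was left out of the pool. Within a class, corrected counts were summed over cells per library and scaled to CPM, and log2 ratios of the RP81 over the empty-particle library used a pseudocount of 0.5 counts. With 1 library per group no test, standard error or count of changed genes was computed, and since the values are not raw counts no counting interval is given for a gene.

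The rule for named genes was written before the data were examined. Eligible genes had at least 50 counts over both libraries, and at least 50 CPM and a count in at least 10% of cells in the higher library. Mitochondrially encoded, ribosomal protein, haemoglobin, sex-linked and unnamed gene models were left out. The 12 highest and 12 lowest ratios were named in the largest class and 5 and 5 in each other class with at least 100 cells per library, down to 1.5-fold. The rule as written ranked by the bound of a counting interval; as the values are corrected counts, the ratio itself was ranked instead. Members of the necroptosis, pyroptosis, cytokine and tubular injury lists, Rnls and Atp2b4 were to be named in any case, and other genes are named as members of their lists or as leading genes of a class. A few genes that the rule names are not reported. A gene with 0 counts in a library has a fold only as a bound, computed with 3 counts over the library's cells of that class.

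The 34 gene lists were fixed before the data were examined. A list's median was computed where at least 5 members had at least 20 counts over both libraries, and was placed among 10000 random lists of the same size matched over 25 bins of mean expression. The percentile describes these libraries and is not a p-value; the central range runs from percentile 2.5 to 97.5. Alternatives were another scaling, equal weighting of cells, count minimums of 5 and 100, lists without the genes that lead a class, a pseudocount of 5, cells of at least 1000 UMIs, a window of 1200 to 3000 UMIs, other denominators, classes from marker scores and removal of doublets. Scaling by TMM factors and thinning of cells need raw counts and were not run. Scrublet, run per library on the corrected counts, marked 3 cells in each library, so its own threshold did not work here and the highest 8% of scores were left out as a further alternative.

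The steps were tested on simulated data made from S2/S3 cells with 10969 genes. Of genes changed 2-fold, 100% came within 0.5 of their true log2 ratio, and of genes lowered to 0.25 of their level, 94%. Of 6063 unchanged genes 0.05% lay beyond 1.5-fold, and 5.5% of unchanged lists fell outside the central range. The simulated sums varied by random counting around 1 profile only, without differences between mice or libraries, free RNA or depth correction. These shares are therefore not error rates for the 2 libraries. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and matplotlib 3.10.9.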

Results

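Kidneys of Rnls knockout mice on the C57BL/6 background were profiled by single-cell RNA sequencing after cisplatin, a nephrotoxic platinum drug. Rnls encodes renalase, a secreted flavoprotein. All mice were 4 months old and received 2 doses of cisplatin at 15 mg/kg, 2 weeks apart. One group received empty mesonanoparticles (MNP) weekly, at 70 mg/kg, over 4 weeks, and the other received mesonanoparticles carrying RP81, a renalase peptide, at the same dose and schedule. The comparison asks how the kidney's cells differ when the particles carry the peptide. Each group is 1 library, so there are no replicates, and the labels do not give the number of mice behind a library. The deposited set held 16733 cells of the empty-particle library and 22543 cells of the RP81 library, each assigned by the authors to 1 of 22 cell classes. The empty-particle library was the deeper one, with a median of 2977 UMIs and 1169 genes per cell against 2293 UMIs and 912 genes in the RP81 library. Levels are in CPM (counts scaled to a total of 1000000 per library and class) of the deposited depth-corrected counts, summed over the cells of a class, and are given for the empty-particle library first, then the RP81 library. Every difference is between these libraries, without a test. Intervals of shares are exact Clopper-Pearson intervals and cover counting error only.

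The RP81 library held a larger share of proximal tubule and distal nephron cells and a smaller share of injured proximal tubule cells. Shares in the text are given for the RP81 library first. Every share depends on the other classes of its library. Leukocytes held 3107 of 22543 cells in the RP81 library and 4870 of 16733 in the empty-particle library. Shares among the cells other than leukocytes were not computed, so tubule and endothelial shares are not read as changes in number. Proximal tubule cells of the S1 and S2/S3 classes, which reabsorb most of the filtered solute, made up 37.0% (95% interval 36.3 to 37.6) of the RP81 library and 23.3% (95% interval 22.7 to 24.0) of the empty-particle library. The class the authors named injured proximal tubule, led by Havcr1 (kidney injury molecule), Ubd, C3 and Vcam1, made up 2.20% (95% interval 2.02 to 2.40) against 6.65% (95% interval 6.28 to 7.04), a 3.02-fold lower share. Among proximal tubule cells of all 4 classes alone, it was 5.20% (95% interval 4.76 to 5.67) against 18.6% (95% interval 17.7 to 19.7).

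Within the tubule, S1 cells differed more than S2/S3 cells. S1 cells were 18.6% of the RP81 library and 8.52% of the empty-particle library, and S2/S3 cells were 18.4% and 14.8%. The classes of the distal convoluted tubule, the connecting tubule and the collecting duct together were 18.2% (95% interval 17.7 to 18.7) against 9.48% (95% interval 9.04 to 9.93), higher by 1.92-fold. The class DCT1, led by Pvalb and the thiazide-sensitive cotransporter gene Slc12a3, had the highest ratio of these, 2.69% against 0.645%. The TAL class, of the thick ascending limb, was 4.26% against 3.32%. With the injured TAL class added it was 7.38% against 8.18%, so the direction depends on that class. Endothelial cells were 11.3% (95% interval 10.9 to 11.7) against 7.47% (95% interval 7.08 to 7.88), though all 10 genes that lead this class were lower in the RP81 library, 5 of them beyond 1.5-fold.

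T cells were 2.68% of the RP81 library against 4.94% of the empty-particle library, and dendritic cells 1.59% against 2.64%. The class the authors named B cell was 1.14% against 0.807%; it is mixed, with immunoglobulin and plasma cell genes such as Jchain and Mzb1 leading it, and 152 of its cells scored as plasma cells and 146 as B cells. These differences depend on the denominator, and none of them is read as a change in number. Among leukocytes alone, a pool whose own size is not compared and which holds the M1 class, T cells were 19.4% (95% interval 18.1 to 20.9) against 17.0% (95% interval 15.9 to 18.1), dendritic cells 11.6% against 9.08%, the B cell class 8.30% against 2.77% and neutrophils 4.70% against 1.56%. Neutrophils among all cells were 0.648% against 0.454%. Macrophages, taken as the infiltrating and M1 classes together, held 3213 cells of the empty-particle library and 1704 of the RP81 library, and the M1 class, led by Ccl4, Ccl3, Tnf, Cxcl2 and Il1b, 1131 and 86. The sizes of macrophages, pooled or by class, are not compared, because more than 5 of their 10 leading genes differed beyond 1.5-fold between the libraries. The 10 genes that lead the pool, C1qa, C1qb and C1qc among them, were all lower in the RP81 library, with a median log2 ratio of -1.27. The endothelial, T cell, B cell and JGA classes, with 5 such genes each, lie exactly at this limit, which was set after the values were seen. By the same rule no size is compared for leukocytes as a whole, the stressed proximal tubule, injured TAL, myofibroblast and podocyte classes, or a small class named Plac8+ macrophage that is led by Timp1 and collagen genes.

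**Figure D1:**
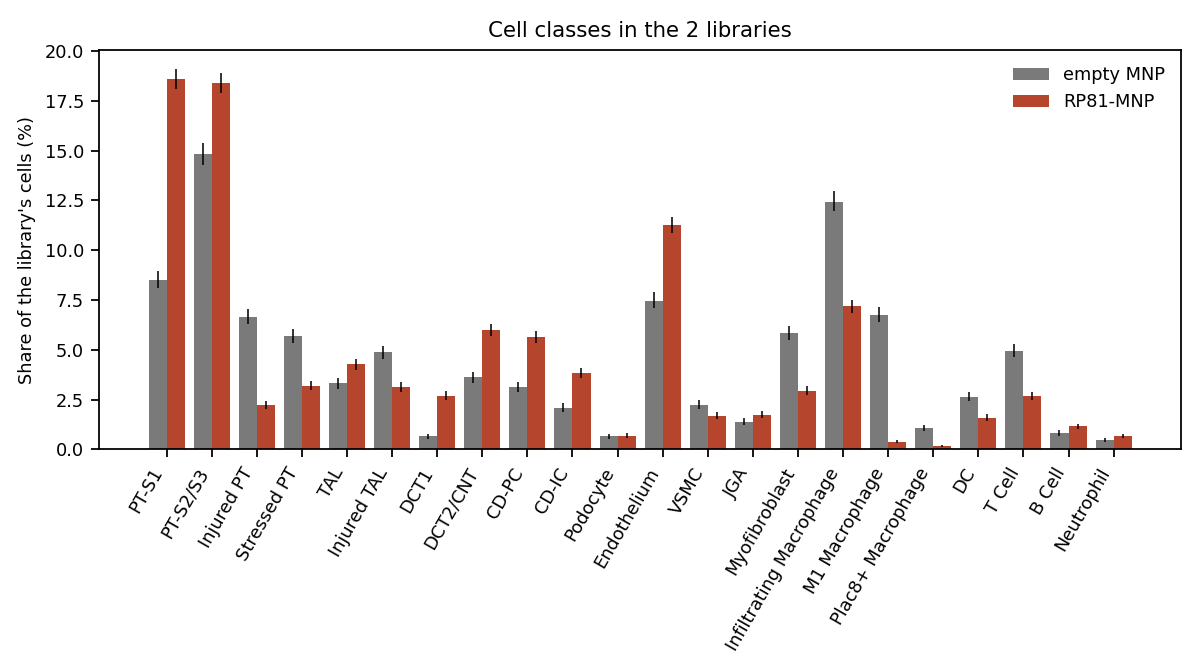
Share of each library's cells (y axis, percent) in each of the 22 cell classes (x axis) for the empty-particle library (grey) and the RP81 library (red); error bars are exact 95% binomial intervals, for counting error only. S1 proximal tubule cells are 18.6% of the RP81 library and 8.52% of the empty-particle library, and injured proximal tubule cells 2.20% and 6.65%.

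In S2/S3 proximal tubule cells, the largest class, Cyp7b1, an oxysterol hydroxylase gene, had the lowest ratio, 15.6-fold lower in the RP81 library (210.3 against 13.4 CPM), and Serpina1f, Slc22a13 and Nat8f6 were 13.9-fold, 11.7-fold and 9.43-fold lower. Cyp7b1 had a count in 14.8% against 1.28% of cells and Serpina1f in 13.1% against 1.13%. For Slc22a13 it was 10.2% against 1.01% and for Nat8f6 11.5% against 1.28%. These ratios rest on a small part of the class and are not read as a fall across all S2/S3 cells. Scd1, the stearoyl-CoA desaturase, was 6.26-fold lower, and the immediate-early genes Jun and Fos 6.27-fold and 5.06-fold lower. The remaining genes among the 12 lowest ratios were Gadd45g, a stress-induced gene, the small heat-shock gene Cryab and the brush-border protease gene Mep1b, at 6.02-fold, 5.73-fold and 3.94-fold, with Spp1, the gene of osteopontin, and Napsa, which leads the class and is not given as a result. Jun, Fos, Gadd45g and Spp1 were at or below the lowest level among T cells, endothelium and TAL cells in the empty-particle library and are read as background. Fos was at 884 CPM in endothelium and 470 CPM in TAL cells of that library, so this level does not show that S2/S3 cells lack it.

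The heat-shock genes Hspa1b and Hsph1 were among the 12 genes with the highest ratios in S2/S3 cells, 3.88-fold and 2.65-fold higher in the RP81 library, though Hspa1b was at background level. Dnase1, the gene of a secreted deoxyribonuclease, was 2.33-fold higher (267 against 624 CPM). Receptor genes were among them, with Met, the hepatocyte growth factor receptor, 2.57-fold and Insr, the insulin receptor, 2.29-fold higher, and Ide, the insulin-degrading enzyme, 2.44-fold higher. Mylk, Col4a4, Cndp1, Ly6e, Palld and Itgb6 made up the rest, from 2.29-fold to 2.74-fold. In the annotation of build GRCm38, Cyp7b1 lies on chromosome 3, 18071950 to 18243338, Ide on chromosome 19, 37268743 to 37337852 and Scd1 on chromosome 19, 44394455 to 44407879.

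The tubular injury genes in S2/S3 cells lay mostly at background level and are not read as expression by these cells. The list was lower in the RP81 library in 14 of 14 members (median log2 ratio -0.95, percentile 0 among 10000 matched random lists, a description of these libraries), but in the empty-particle library 10 of the 14 were at or below the lowest level among T cells, endothelium and TAL. Spp1 was at 525 against 119 CPM in S2/S3 cells and 756 against 409.7 CPM in endothelium. Lcn2 (neutrophil gelatinase-associated lipocalin) was at 18.6 against 3.81 CPM and 43.8 against 12.6 CPM, and Havcr1 at 8.07 against 1.75 CPM and 6.31 against 3.34 CPM, in the same order of classes. Only Krt8 and Dcdc2a were more than 1.5-fold above that lowest level, with log2 ratios of -0.80 and -0.92. For the rest the log2 ratios were -1.28 for Krt18, -1.27 for Anxa2, -1.01 for Cdkn1a, -0.97 for Vcam1, -0.79 for S100a6, -0.51 for Lgals3, -0.51 for Cd24a, -0.51 for Clu and -0.12 for Tnfrsf12a. Targets of p53, the DNA damage response factor, were lower in 14 of 18 members (median log2 ratio -0.53, percentile 0), with 6 of 18 at or below background, Btg2 among them. Btg2 and Gdf15 were 6.90-fold and 2.92-fold lower, while Mdm2 and Ccng1 were at log2 ratios of 0.05 and -0.19.

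Members of the unfolded protein response list were higher in 12 of 14 cases in S2/S3 cells (median log2 ratio 0.43, percentile 99.7). In the empty-particle library 7 of 14 were at or below the lowest level among T cells, endothelium and TAL cells, which also make these genes. Only Xbp1 and Herpud1 were more than 1.5-fold above it, at log2 ratios of -0.02 and 0.48, and the list's median was 0.01 in T cells and -0.23 in endothelium. Hspa5, the endoplasmic reticulum chaperone BiP, was at 260.5 against 374 CPM, Dnajb9 at 40.9 against 67.3 CPM and Creld2 at 15.3 against 27.1 CPM. Atf3, which is also an immediate-early gene, went the other way and was 10.2-fold lower, at background level. In S1 cells 12 of 14 members were higher (median log2 ratio 0.59, percentile 100), with Hspa5 at 229 against 420.3 CPM; 6 of 14 were at or below that lowest level and 4 more than 1.5-fold above it, 1 of them lower in the RP81 library.

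Solute transporters of the proximal tubule were slightly higher in S2/S3 cells of the RP81 library (14 of 20 members; median log2 ratio 0.20, percentile 99.5). The organic anion transporter gene Slc22a30 was at 179 against 340.0 CPM, the phosphate transporter gene Slc34a1 at 2936 against 3926 CPM and Lrp2, which encodes the endocytic receptor megalin, at 1022 against 1437 CPM. Abundant proximal tubule transcripts outside the transport list were not higher, with 4 of 14 members higher (median log2 ratio -0.49, percentile 3.58). All 13 measured mitochondrially encoded genes of oxidative phosphorylation were higher (median log2 ratio 0.36, percentile 99.9) and all 23 nuclear ones lower (median log2 ratio -0.35, percentile 39.5). Fatty acid oxidation and peroxisome genes gave a median of -0.11 (percentile 49.7), hypoxia and glycolysis genes a median of -0.35 (percentile 4.29), and oxidative stress response genes a median of -0.33 (percentile 7.28). Genes of ferroptosis defence were lower in 8 of 9 members (median log2 ratio -0.57, percentile 0.190), Gpx4 and Fth1 at log2 ratios of -0.80 and -0.58. The metallothionein genes Mt1 and Mt2 were at log2 ratios of 0.09 and -0.35.

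The necroptosis and pyroptosis lists lay inside the range of random lists in S2/S3 cells. The necroptosis list had 5 of 8 members lower (median log2 ratio -0.09, percentile 22.0) and 4 of 8 at or below background; Casp8 and Fadd alone were more than 1.5-fold above it. The ratios were lower for Casp8, Tnfrsf1a, Traf2, Fadd and Birc3, at log2 ratios of -0.65, -0.36, -0.31, -0.12 and -0.06. Birc2, Ripk1 and Cyld were at 0.33, 0.37 and 0.42. The pyroptosis and inflammasome list had 5 measured members, all lower (median log2 ratio -0.46, percentile 8.18). Il1b was at a log2 ratio of -2.21, Pycard at -0.49, Nlrc4 at -0.46, Gsdme at -0.38 and Il18 at -0.24, with Il1b and Pycard at background level.

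Cytokine and chemokine transcripts in S2/S3 cells were at background level for the most part. The list was lower in 14 of 17 members (median log2 ratio -1.25, percentile 0), but 11 of the 17 were at or below the lowest level among T cells, endothelium and TAL in the empty-particle library. With members of at least 100 corrected counts alone the median was 0.41, and in cells with 1200 to 3000 UMIs it was -0.18. More than 1.5-fold above that level were 5 members: Cxcl1, Il18 and Il34 at log2 ratios of -2.75, -0.24 and -0.22, and Cxcl12 and Cx3cl1 at 0.41 and 0.62. The others, not read as made by S2/S3 cells, were Ccl7, Ccl4, Ccl3, Ccl2, Cxcl2, Ccl12, Il1b and Ccl5 at -4.85, -3.57, -3.57, -3.32, -2.93, -2.92, -2.21 and -1.25, and Cxcl16, Cxcl10, Tgfb1 and Tnfsf10 at -0.63, -0.33, -0.09 and 0.91. Transcripts that macrophages make were lower in the same cells, with MHC class II genes at a median of -1.48 (percentile 0) and the resident macrophage list at -1.37 (percentile 0), where 5 of 6 and 5 of 10 members were at or below background. In S2/S3 cells with 1200 to 3000 UMIs the tubular injury list was at -1.53 and the transport list at 0.58.

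Among the remaining lists in S2/S3 cells, many members were at or below the lowest level among T cells, endothelium and TAL cells in the empty-particle library and are read as background: 5 of 10 complement, 9 of 13 NF-kB response, 8 of 9 interferon response, 10 of 14 matrix, 7 of 10 TGF-beta response and 4 of 6 senescence genes. Complement genes had a median log2 ratio of -0.91 and NF-kB response genes -0.85, each at percentile 0, while interferon response genes were at -0.67 (percentile 0.805). Cell cycle genes were lower in 7 of 7 members (median log2 ratio -0.84, percentile 0.0200) and senescence genes in 3 of 6 (median log2 ratio -0.51, percentile 2.75). Matrix genes gave -0.53, TGF-beta response genes 0.34 and genes of angiotensin and catecholamine handling 0.08. The metallothionein, haemoglobin and platelet lists had fewer than 5 measured members in every class and have no median.

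In S1 cells Cpn1, Lpl, Atp11a and Itgb6 were 2.84- to 8.72-fold higher in the RP81 library, Cpn1 (a carboxypeptidase N subunit) at 6.33 against 56.5 CPM, and Tmem252, AY036118 and Tmem37 were 2.29- to 2.86-fold lower. Cd74 and Hspa1b, also named there, were at or below the level in T cells, endothelium and TAL cells and are read as background, Cd74 at 164 against 48.6 CPM in S1 cells and 359.6 against 187 CPM in endothelium. The tubular injury list in S1 cells had 11 of 12 members lower (median log2 ratio -0.43, percentile 0.0500), with 9 of the 12 at or below background in the empty-particle library. In injured proximal tubule cells Cpn1, Ide, Edem1, Slc22a30 and P3h2 were 2.53- to 21.3-fold higher, Cpn1 at 7.04 against 154 CPM. On the other side Atf3, Cxcl2, Fos, Cxcl1 and Fosb were 4.12- to 7.19-fold lower. Tubular injury genes were lower in 14 of 17 members in injured cells (median log2 ratio -0.57, percentile 0), with all 17 more than 1.5-fold above background. Without the genes that lead the class, Havcr1, Spp1 and Vcam1 among them, the median was -0.58. Krt18 was at 247 against 106 CPM, Lcn2 at 126 against 75.1 CPM, Sox9, a gene of injured tubule cells, at 99.3 against 59.9 CPM and Clu at 360.1 against 363 CPM. Necroptosis genes had 7 of 8 members higher there (median log2 ratio 0.31, percentile 80.8). Stressed proximal tubule cells had 16 of 16 p53 targets lower (median log2 ratio -0.82, percentile 0, with all genes at a median of -0.22). The 10 genes that lead this class were all lower too, with a median of -1.09, so the p53 list was no lower than those. There S100g and Acss1 were each 2.33-fold higher, and Nat8f6, Noct, Nat8f2 and Tcim were 4.17- to 14.9-fold lower. S100g leads the DCT2/CNT class and is not read as made by stressed proximal tubule cells. Klk1, Wfdc15b, Tmem213 and H2-Ab1, also named there, were at background level.

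Several transcripts differed the same way in nearly every class. Dissociation stress genes were lower in all 19 classes with at least 100 cells per library, with medians from -2.41 to -0.67. In cells with 1200 to 3000 UMIs these medians ran from -2.24 to -0.58, and in DCT1 cells the median went from -2.14 to -1.03. In S2/S3 and in S1 cells 19 of 21 of these genes were at or below the lowest level among T cells, endothelium and TAL cells. NF-kB response genes had medians below 0 in 19 classes and tubular injury genes in 19, leukocyte classes among them, though in injured proximal tubule cells with 1200 to 3000 UMIs the NF-kB median was 0.015. Mitochondrially encoded genes were higher in 19 classes. The mitochondrial share of counts in infiltrating macrophages was 24.7% in the RP81 library against 13.5%, in T cells 27.5% against 18.6%, and in S2/S3 cells 35.1% against 30.0%. Proximal tubule transcripts made up 3.67% in the RP81 library against 1.92% of counts in T cells and 2.88% against 1.00% in myofibroblasts, neither of which makes them. Egf in endothelium and infiltrating macrophages, Kl in dendritic cells and Wfdc15b in the B cell class, named as higher there, were at or below their level in classes of other lineages. Slco1a1, which leads the S2/S3 class, was named as higher in endothelium, myofibroblasts and smooth muscle and is not read as made there. Dnase1 was named among the highest ratios in 12 classes and Atf3 among the lowest in 11. Scaling to counts outside mitochondrially encoded and ribosomal protein genes raised the median of all genes by 0.238 in myofibroblasts, 0.191 in stressed proximal tubule cells and 0.181 in endothelium on the log2 scale. This scaling turned none of the 160 recomputed list medians outside the range of random lists. It shifts all genes of a class alike, by less than the 1.5-fold needed for naming, so none of the 204 named ratios could turn.

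**Figure D2:**
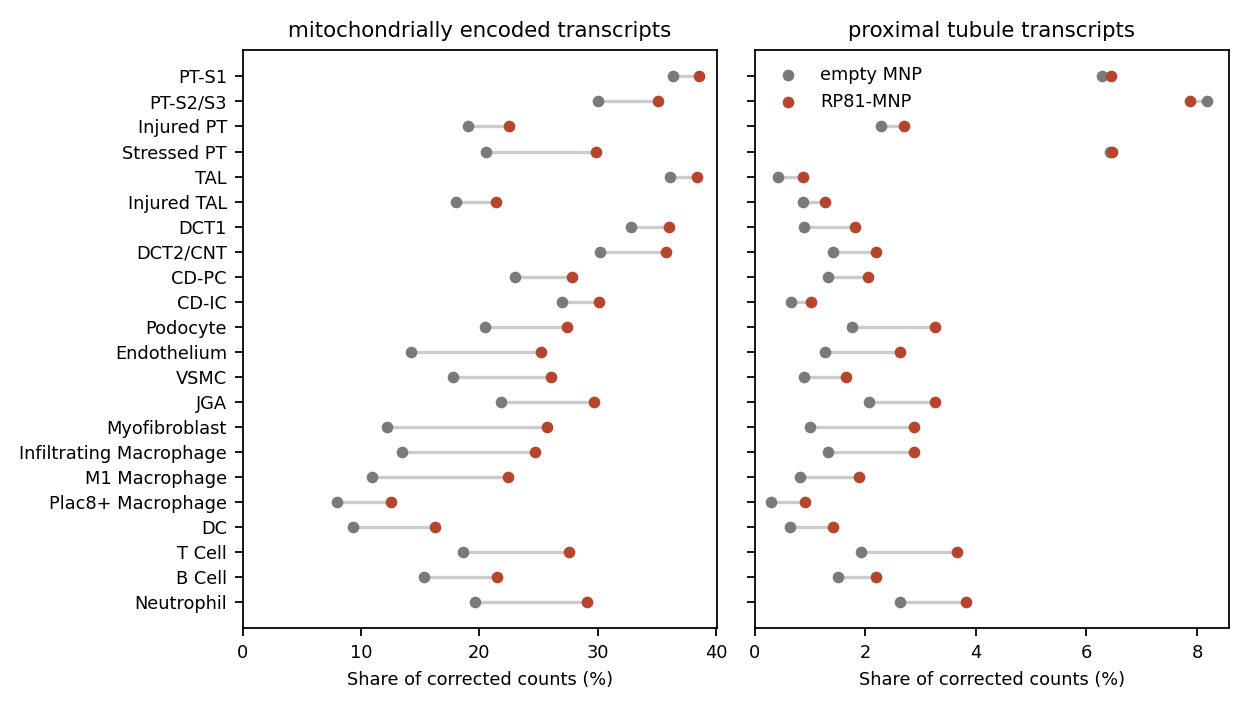
Share of corrected counts (x axis, percent) from mitochondrially encoded genes (left) and from 2 lists of proximal tubule transcripts (right) in each cell class (y axis), for the empty-particle library (grey) and the RP81 library (red), 1 value per library and class. The mitochondrial share in myofibroblasts is 12.2% and 25.7%, and the proximal tubule share in T cells 1.92% and 3.67%.

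In the thick ascending limb, the distal convoluted tubule and the collecting duct, Atf3, a stress-induced transcription factor gene, was among the 5 lowest ratios of each class. In TAL cells Socs3, Fos, Atf3, Zfp36 and Gdf15 were 7.90- to 13.8-fold lower, and Dnase1, Slc7a13, Maf and Kcnj15 were 3.77- to 6.96-fold higher; these higher genes were all at or below their level in T cells and endothelium and are read as background. Of the injured TAL class, 494 cells scored as loop of Henle, 462 as injured proximal tubule and 222 as plasma cells. The injured proximal tubule markers include general injury genes such as Lcn2, which leads this class. The plasma cell markers also marked 325 S1 cells. These scores therefore do not show which cells the class holds, and its ratios are not read as those of TAL cells. There the higher genes were others: Lypd2, Corin and Angpt2, the gene of angiopoietin-2, were at 71.2 against 378 CPM, 26.1 against 146 CPM and 60.1 against 279 CPM, and Rnf186 and Bcat1 were 4.91-fold and 4.63-fold higher. The lower genes of that class, Atf3, Klf2, Serpinb1a, Socs3 and AY036118, with AY036118 at background level, were 3.49- to 4.04-fold lower. In DCT1 cells Cyr61, Atf3, Zfp36, Gdf15 and Egr1 were 6.13- to 8.90-fold lower. G6pc, a gluconeogenic enzyme gene of the proximal tubule, had 0 counts in the 108 DCT1 cells of the empty-particle library and was at least 5.26-fold higher in the RP81 library. Hykk, Cldn2, Slc13a3 and Cd36 were also among the highest ratios, on 1, 1, 3 and 3 corrected counts in the empty-particle library. Slc13a3 belongs to the proximal tubule transport list, and these ratios are not read as changes within DCT1 cells. In cells with 1200 to 3000 UMIs Cd36 was at a log2 ratio of -0.30. In the class of late distal convoluted and connecting tubule Lcn2, Atf3, Ier2, Fos and Egr1 were 5.45- to 8.71-fold lower, and Egf, Acsm3, Sardh, Dnase1 and Tmem174 were 2.69- to 3.68-fold higher. Acsm3 leads the S2/S3 class and Egf the TAL class, so neither ratio is read as a change within this class.

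Principal cells of the collecting duct, led by the aquaporin genes Aqp2, Aqp3 and Aqp4, had higher Id4, an inhibitor of transcription factor binding, at 33.8 against 148 CPM, and Stc1, which encodes the hormone stanniocalcin-1, at 65.8 against 236 CPM. Dnase1, P3h2 and Enpp2 were 3.73-fold, 2.86-fold and 2.85-fold higher, and Cebpd, Socs3, Ctgf, Ier3 and Atf3 were 4.85- to 15.0-fold lower. Intercalated cells also had higher Stc1 (35.4 against 181 CPM); Dnase1, Actr1a, Dgcr2 and Vkorc1l1 followed, from 2.66-fold to 3.28-fold higher, though Dgcr2 was at a log2 ratio of -0.38 in cells with 1200 to 3000 UMIs. Among their lower genes Cebpd, Socs3, Ier3, Atf3 and Cyr61 had log2 ratios of -2.44, -2.41, -2.23, -2.13 and -2.04.

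Macrophages of the RP81 library held less cytokine and chemokine RNA. In the infiltrating class 21 of 25 measured members were lower (median log2 ratio -1.10, percentile 0), the monocyte chemokine genes Ccl2 and Ccl7 at 291 against 62.5 CPM and 274 against 35.7 CPM. The 10 genes that lead this class were also all lower, with a median log2 ratio of -0.78, and the 100 transcripts most specific to it, cytokines left out, were at -0.79. In the pool, which includes the M1 class that came mostly from the empty-particle library, 23 of 26 were lower (median log2 ratio -2.40, percentile 0), and without the genes that lead the pool or either of its classes the median was -1.14. Values of single genes are of the infiltrating class alone, since the pool also holds the mix of classes and several of these genes lead the M1 class. The chemokine genes Ccl8 and Ccl12 were at 897 against 175 CPM and 962 against 226 CPM, the neutrophil chemokine gene Cxcl2 at 104 against 33.6 CPM and Il1b at 289 against 168 CPM. Cxcl1, Il1a, Cxcl10, Ccl3, Tnf, Ccl9 and Ccl4 were 3.90-fold, 2.93-fold, 2.82-fold, 2.81-fold, 2.69-fold, 2.57-fold and 2.47-fold lower, Cxcl1 and Il1a at under 6 CPM. Il6, Ccl5, Ccl6, Csf1, Il18, Cxcl9, Cxcl16 and Tgfb1 were at log2 ratios of -1.10, -1.08, -1.01, -0.96, -0.94, -0.67, -0.59 and -0.37. Cxcl12, Tnfsf10, Cx3cl1 and Il34, all at under 12 CPM, were at 0.07, 0.15, 0.33 and 0.40. Il10 was measured in the pool alone, with 61 corrected counts in the empty-particle library and 0 in the RP81 library.

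**Figure D3:**
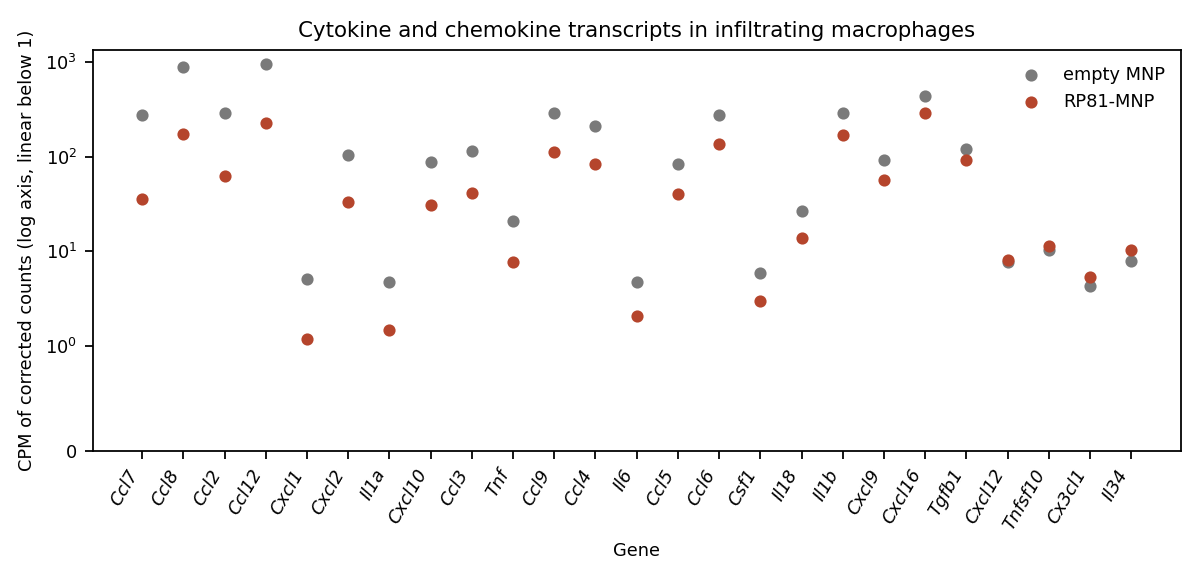
CPM of corrected counts (y axis, log scale above 1 and linear below) of the 25 measured cytokine and chemokine genes (x axis) in infiltrating macrophages of the empty-particle library (grey) and the RP81 library (red), 1 value per library without error bars. Ccl8 stands at 897 and 175 CPM and Cxcl2 at 104 and 33.6 CPM.

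Several other lists were lower in infiltrating macrophages. The 10 genes that lead this class were at a median log2 ratio of -0.78, and the 100 transcripts most specific to it at -0.79. Resident macrophage, MHC class II and infiltrating monocyte genes were less low than that. Complement genes, with leading genes included, and pyroptosis genes were about as low. Interferon response genes were lower in 22 of 22 members (median log2 ratio -0.97, percentile 0) and complement genes in 10 of 11 (median log2 ratio -0.78, percentile 0.0600; -1.05 without the genes that lead the class). The resident macrophage list gave a median of -0.60 (percentile 0.130; -0.46 without those genes), with Apoe at 28520 against 10757 CPM, and MHC class II gave a median of -0.59 (percentile 1.45). The repair-associated list was lower in 12 of 14 members (median log2 ratio -0.87, percentile 0), and the infiltrating monocyte list in 7 of 9 (median log2 ratio -0.49, percentile 3.12), Ccr2 at 439 against 219.8 CPM. Among pyroptosis and inflammasome genes 10 of 11 members were lower (median log2 ratio -0.78, percentile 0.0200), with the interleukin-1 receptor antagonist gene Il1rn 5.61-fold lower at under 16 CPM. Aim2, Nlrp3, Il18, Pycard, Nlrc4, Casp4, Gsdmd and Casp1 had log2 ratios of -1.12, -0.96, -0.94, -0.88, -0.78, -0.74, -0.73 and -0.61, and Gsdme 0.25. Neutrophil genes gave a median of -0.08 (percentile 51.7). The named genes Ccl7, Ccl8, Lyz1, Ccl2 and Socs3 were 4.38- to 7.64-fold lower, and Dnase1, Pcx, Bpnt1 and Them7 were 3.00- to 3.61-fold higher.

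T cells of the RP81 library held less RNA of activation and exhaustion genes, all 10 measured members being lower (median log2 ratio -1.40, percentile 0). Of the 10 genes that lead the class 9 were lower, with a median of -0.54, so a part of this is shared by the class's own leading genes. Tnfrsf4 was at 183 against 49.0 CPM, the inhibitory receptor gene Ctla4 at 66.5 against 18.9 CPM and Foxp3, the regulatory T cell factor, at 48.1 against 15.5 CPM. Cytotoxic genes were not lower as a group (7 of 11 members higher; median log2 ratio 0.13, percentile 78.8), with the granzyme gene Gzma at 60.8 against 230.2 CPM and Ifng at 13.9 against 10.3 CPM. The class is mixed, with 604 cells in the RP81 library and 827 in the empty-particle library. In that order, 357 and 646 scored as T cells, 126 and 91 as natural killer cells, and 26 and 6 as proximal tubule cells. Neither list is therefore read as a change within T cells. Among named genes H2-Eb1, Gadd45b, Ppp1r15a, Hspa1a and Junb were 4.32- to 8.46-fold lower, and Dnase1, Dnajc12, Pcx, Prodh and Hykk were 3.20- to 4.58-fold higher. In the mixed class named B cell Ccl4, Ncf1, Siglech, Plac8 and Nfkbia were 4.63- to 10.7-fold lower, and Dnase1, Ell2, Calb1 and Ascc1 were 2.93- to 7.15-fold higher. Ccl4 and Siglech are genes of myeloid and plasmacytoid dendritic cells, and 19 cells of that class scored as dendritic cells and 15 as monocytes, so these ratios are not read as changes within B cells. Calb1 leads the DCT2/CNT class and is not read as made by B cells. In dendritic cells Grasp, Ccl4, AA467197, Nr4a1 and Ahr were 3.70- to 6.08-fold lower, and Klk1, Igkc, Them7 and Dnase1 were 3.97- to 5.22-fold higher. Over both libraries, Klk1 was at 19714 CPM in late distal convoluted and connecting tubule cells and Igkc at 145968 CPM in the B cell class. Both lead those classes and are not read as made by dendritic cells.

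Endothelial cells of the RP81 library had lower interferon response and immediate-early transcripts. All 22 measured interferon response genes were lower (median log2 ratio -0.85, percentile 0, with all genes at -0.28), Ifit3 at 159 against 57.1 CPM and Irf7 at 164 against 71.7 CPM. Endothelial marker genes were lower in 12 of 12 members (median log2 ratio -0.54, percentile 0.770; -0.48 without the genes that lead the class). Of the named genes Atf3, Ier3, Egr1, Fos and Socs3 were 7.78- to 13.5-fold lower, Fos at 884 against 104 CPM, and Dnase1, Slco1a1, Ugt2b38 and Nudt19 were 2.95- to 4.04-fold higher.

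Myofibroblasts of the RP81 library had lower matrix transcripts in 26 of 28 members (median log2 ratio -0.95, percentile 0, with all genes at -0.31). The 10 genes that lead the class, Col1a1 and Timp1 among them, were all lower as well, with a median log2 ratio of -1.06, so the matrix list was no lower than the class's own leading genes. The mitochondrial share of counts in this class was 25.7% in the RP81 library against 12.2%. Without the leading genes the matrix median was -0.91. Acta2, which encodes smooth muscle actin, was at 562 against 224 CPM, while the fibroblast gene Pdgfrb was at 296 against 311 CPM. TGF-beta response genes were lower in 12 of 14 members (median log2 ratio -0.94, percentile 0.0300). Igfbp3, a binding protein for insulin-like growth factors, was 5.36-fold higher (169 against 908 CPM), with Dnase1, Slc22a30, Slco1a1 and Cd36 next. Among the lower genes Hp, Cyr61, Rgs16 and Ptn were 6.82- to 13.4-fold lower.

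The class the authors named JGA, for the juxtaglomerular apparatus, is mixed: Notch3, Rgs5 and Ndufa4l2, genes of pericytes and mesangial cells, lead it beside Ren1, the renin gene, and 365 of its 620 cells scored as fibroblast or mesangial. Ren1 leads the class, so its level there is not given as a result. Bpnt1, Insr, Tkfc and Sardh were 3.52-fold to 4.32-fold higher there, and Atf3, Cdc42ep3, Zfp36, Fos and Cebpd were 3.85- to 4.67-fold lower. In smooth muscle cells Cebpd, Atf3, Nr4a2, Socs3 and Rgs17 were 8.86- to 11.1-fold lower, and Slco1a1, Dnase1, Slc5a3, Wfdc15b and Myh6 were 4.08- to 5.25-fold higher. Wfdc15b leads the TAL class and Slc5a3 the pooled TAL classes, so neither is read as made by smooth muscle. In podocytes Atf3, Egr1, Fos, Junb and Fosb were 12.8- to 20.2-fold lower, and Adamts5, Epas1, Ptn, Flt1 and Gimap4 were 5.11- to 8.40-fold higher. Flt1, a receptor gene for vascular endothelial growth factor, belongs to the endothelial list, of which all 9 measured members were higher in podocytes (median log2 ratio 2.02, percentile 100). This list was not particular to podocytes: its median was above 0 in 14 of 17 classes, at 1.37 in principal cells and 1.71 in smooth muscle. At or below background were 0 of 9 members in podocytes, 1 of 8 in smooth muscle and 4 of 9 in principal cells. The 10 genes that lead the podocyte class were all lower in the RP81 library, with a median log2 ratio of -0.80.

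Rnls itself, on chromosome 19 from 33137747 to 33392295 in GRCm38, was not analysed here, so the knockout label could not be checked from expression. Atp2b4, which encodes a plasma membrane calcium pump described as a renalase receptor, was nearly absent from S2/S3 cells (0.526 against 0.928 CPM). It was highest in smooth muscle (135 against 178 CPM) and in the DCT2/CNT class (119 against 123 CPM), followed in the empty-particle library by DCT1 (65.2 against 51.2 CPM). It was at 46.4 against 30.4 CPM in endothelium and 35.1 against 61.2 CPM in the JGA class, above DCT1 in the RP81 library.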

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

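The results in this part were picked out because a gene list lay above the range of matched random lists in 1 cell class and below it in another; no test was run on them, and the differences between classes were not tested. Values are median log2 ratios, RP81 library over empty-particle library, in the classes with the highest and the lowest median among those outside the random range.

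Endothelial genes were at 2.02 in podocytes (9 of 9 members higher) and at -0.91 in the mixed class named B cell (8 of 10 members lower). They were above 0 in 14 of 17 classes, among them principal cells at 1.37 (4 of 9 members at or below background) and smooth muscle at 1.71 (1 of 8), and the 10 genes that lead the podocyte class were all lower in the RP81 library. TGF-beta response genes were at 1.22 in podocytes (3 of 5 members higher), where the mean was 0.08, and at -1.11 in the mixed class named B cell (5 of 7 members lower). Genes of angiotensin and catecholamine handling were at 1.09 in principal cells of the collecting duct (7 of 8 members higher) and at -0.51 in the thick ascending limb (4 of 5 members lower). Fatty acid oxidation and peroxisome genes were at 0.62 in dendritic cells (13 of 18 members higher) and at -0.53 in stressed proximal tubule cells (17 of 21 members lower). At or below background were 10 of 18 members in dendritic cells and 0 of 21 in stressed proximal tubule cells. In dendritic cells Acaa1b, Cyp4a10 and Cyp4a14 alone were more than 1.5-fold above it, 2 of them lower in the RP81 library. Oxidative stress response genes were at 0.45 in dendritic cells (11 of 13 members higher) and at -0.58 in stressed proximal tubule cells (13 of 14 members lower). In dendritic cells 6 of the 13 were at or below background and 3 more than 1.5-fold above it, 1 of them lower in the RP81 library. Hypoxia and glycolysis genes were at 0.29 in infiltrating macrophages (9 of 15 members higher) and at -0.48 in the late distal convoluted and connecting tubule (11 of 13 members lower). In infiltrating macrophages the hypoxia median was -0.018 with members of at least 100 corrected counts. There 5 of the 15 members were at or below background and 3 more than 1.5-fold above it, 1 of them lower in the RP81 library. Ferroptosis defence genes were at 0.21 in smooth muscle cells (4 of 6 members higher) and at -0.57 in S2/S3 proximal tubule cells (8 of 9 members lower). In smooth muscle 1 of 6 members was at or below background. Slc3a2 alone was more than 1.5-fold above it there, and it was lower in the RP81 library.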

How the results depend on the processing

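Chosen only after the data were examined were the depth window of 1200 to 3000 UMIs, leaving out the highest 8% of doublet scores, the shares within a lineage, the pooling of macrophage classes and leaving out the genes that lead a class; the other alternatives were fixed before. Weighting each cell equally, scaling to counts outside mitochondrial and ribosomal protein genes, and leaving out the cells marked by Scrublet kept the direction of all 204 gene ratios. The scaling shifts all genes of a class alike, by at most 0.238 (log2), less than the 1.5-fold needed for naming. It could therefore turn no named ratio, and leaving out the 3 cells marked per library could hardly change any. List medians were recomputed in S2/S3, S1 and injured proximal tubule cells, pooled and infiltrating macrophages, endothelium, myofibroblasts and T cells: 160 lay outside the range of random lists and 65 inside. Those 3 alternatives turned none of the 160, while equal weighting turned 4 and the scaling 8 of the 65. Leaving out the highest doublet scores turned no gene ratio and none of the 157 medians outside the range that it gave, turned 6 of 63 inside, and moved 4 gene ratios and 6 medians.

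Shares are given as RP81 over empty-particle library. S1 and S2/S3 proximal tubule cells went from 1.58 to 1.42 with classes from marker scores; outside the largest class, S2/S3, S1 cells alone remain, at 2.28 against 2.18 among all cells. Injured proximal tubule cells went from 0.331 to 0.279 among proximal tubule cells. The sizes of macrophages and leukocytes are not compared under any setting. Distal nephron and collecting duct cells went from 1.92 to 2.12 in cells of at least 1000 UMIs.

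Depth moved the most values: in the window, 75 gene ratios and 50 list medians moved; 2 gene ratios turned, as did 2 of 150 list medians outside the random range and 11 of 57 inside. In S2/S3 cells the tubular injury median was -1.53 there, the cytokine median -0.18 and the transport median 0.58. The macrophage cytokine median was -1.84 and the endothelial interferon median -0.59. In injured proximal tubule cells NF-kB response genes turned to 0.015 and MHC class II genes to 0.10, and Dgcr2 in intercalated cells turned to -0.38 and Cd36 in DCT1 cells to -0.30. With members of at least 100 corrected counts the S2/S3 cytokine median turned to 0.41 and the endothelial median of angiotensin and catecholamine genes to -0.035 and the infiltrating macrophage median of hypoxia genes to -0.018; with at least 5 counts the S1 TGF-beta median turned to -0.0027. A pseudocount of 5 took the macrophage cytokine median to -2.12, and leaving out leading genes took it to -1.14 and turned no median. Apart from the smaller set of members under a higher count minimum, the cause was not tested.

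Scaling by edgeR TMM factors and thinning to 1 depth need raw counts and were not run. Rnls, in all cells or in proximal tubule cells alone, was not analysed here.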

Other observations

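Among the tests in this part, those of handling, depth and dilution for the stress genes, of depth and of dilution in the infiltrating class for the macrophage cytokines, and of the chromosome 19 segment were chosen only after the result was seen.

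Beyond the comparisons above, the cell death lists were read in every class. Pyroptosis and inflammasome genes had a median below 0 in all 7 classes with enough members, below the range of random lists in 5, and necroptosis genes in 13 of 17, below that range in 3. The median of all genes was itself below 0 in 14 of 19 classes. In infiltrating macrophages Zbp1, a sensor of nucleic acids, was 3.10-fold lower and Birc3 1.67-fold lower, while Ripk3 was at a log2 ratio of -0.16. Targets of p53 had a median below 0 in all 18 classes with enough members, below the random range in 14. In the class the authors named JGA all 11 measured interferon response genes were lower, with a median of -1.25.

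Proximal tubule transcripts and mitochondrially encoded transcripts were higher in the RP81 library in classes that do not make the former, such as T cells and macrophages. In 10 of the 12 classes outside the tubule, the mitochondrial gain per proximal tubule gain lay within 0.5 to 2 times the ratio in proximal tubule cells, with a median quotient of 1.49, as RNA released by those cells would give. In S2/S3 cells, though, the mitochondrial share changed by 5.07 points and that of proximal tubule transcripts by -0.31. In stressed proximal tubule cells the changes were 9.31 and 0.04 points. The quotient therefore cannot tell released RNA from a mitochondrial rise of another source. The transport list in T cells, at 0.88, was at 1.10 in cells of 1200 to 3000 UMIs. That argues against depth correction as the whole cause. Leaving out the highest doublet scores gave 0.80, but these scores were not shown to find doublets here, so doublets stay open. In the T cell class 26 cells of the RP81 library and 6 of the empty-particle library scored as proximal tubule, and these cells were kept. Free RNA in the droplets is a candidate source, so tubule genes such as Slc22a30 and Slco1a1 in other classes may not be made there. More intact proximal tubule cells in the kidneys given RP81 remain an untested reason for more such RNA.

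Immediate-early genes such as Fos and Atf3 were lower in the RP81 library in all 19 classes by their median. If handling before lysis alone set this, heat-shock members should follow, and their median was lower in 11 of 19 classes, which leaves handling open. For the whole stress list, heat-shock members included, the median over classes was -1.05 among cells of 1200 to 3000 UMIs against -1.45, so depth correction may hold a part. Scaling outside mitochondrial and ribosomal genes left the median of that list at -1.40. It shifts all genes of a class alike, by at most 0.238, so it could not have removed a fall of this size. Ribosomal protein counts were taken out too. Their median share per T cell was 23.8% in the empty-particle library and 15.1% in the RP81 library, against the direction of mitochondrial transcripts. Dilution by mitochondrial transcripts alone was therefore not tested. An effect of RP81 on stress signalling was not tested and cannot be told apart from a library's handling, since each treatment is 1 library.

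Cytokine genes were lower in macrophages of the RP81 library, with a median of -2.40 in the pool and -1.10 in the infiltrating class, so the pooled value partly follows the mix of classes. The 100 transcripts most specific to macrophages, cytokines left out, were at -0.82 in the pool, and those of the infiltrating class at -0.79, so dilution by free RNA may hold a part. In the depth window the pooled median was -1.84, which argues against depth correction as the whole cause. Macrophages without an immediate-early count gave -1.02, but only 0.707% of M1 cells of the empty-particle library are such cells, so this removes nearly all of the M1 class and says nothing on activation during digestion. Handling and an effect of RP81 on macrophages cannot be told apart, since each treatment is 1 library.

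Several tubule genes named above lie near Rnls on chromosome 19, among them Cpn1, Ide, Scd1 and Actr1a. A candidate explanation is a passenger segment of the donor strain around the targeted locus that differs between the mice of the libraries. Of 666 tubule genes beyond 2-fold, 19 lay within 15 Mb of Rnls against 10.7 expected from all eligible genes, a ratio of 1.78, which neither reaches nor excludes what such a segment would give. The 19 include Cpn1, Ide, Scd1 and Actr1a, which prompted the question, so the count is not independent of it. They also include Ifit2 and Ifit3b, neighbouring genes of the interferon response list. Whether the mice differ in this segment cannot be read from expression alone.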
